A study of Rattus norvegicus with 56 samples.

How the data were processed

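Liver RNA of 56 rats was measured by sequencing. Per the labels, total RNA was made into stranded libraries with a kit that removes ribosomal RNA, and sequenced on an Illumina HiSeq 4000; the molecule label reads polyA RNA. The source label reads mouse liver, while the organism label reads rat. The series title also names the pancreas, which is not analysed here. The submitters' processing notes name FastQC, STAR, featureCounts, Subread and DESeq2 and the genome build rn6, with no versions or settings.

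The deposited count table by the authors holds raw counts of reads per gene, with no normalization. Its 17337 genes are identified by symbol, and its header is 1 name shorter than its rows, so columns were taken in order after the gene column. The table holds 26 symbols turned into dates and 2 duplicated symbols, which were kept as separate entries. The authors also deposited 12 tables, each comparing a diet with CON within a sex and time. Per the file headers, their mean signal (coverage) is the mean of counts divided by DESeq2 size factors. Per the file headers, their log2 values are log2 fold changes of the diet over CON, and each adjusted p-value is from the authors' DESeq2 fit. In these tables each call of a higher or lower gene has an adjusted p under 0.05 and a log2 fold change of at least 1 in size. The tests here start from the counts; the authors' tables were used only for a comparison of calls.

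Libraries were grouped by the labels for sex, time and diet into 16 groups of 3 or 4. Genes were kept with edgeR's filterByExpr, which left 11047; 2487 genes had no read in any library. All 56 libraries entered a single fit in edgeR 4.0.16 (R 4.3.3) with 1 mean per group, TMM scaling, robust dispersions and quasi-likelihood F tests, with 40 residual degrees of freedom. The 31 comparisons were contrasts of this fit: a diet against CON, or IUGR-HFhf against HFhf, in each stratum of sex and time and as the mean of the 4 strata, ZT16 against ZT4 within each diet, males against females in CON, and differences of a diet effect between sexes and between times. Tests were two-sided, and p-values were adjusted within each comparison by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors are the log2 fold change divided by the root of F. CPM values use TMM-scaled library sizes. With fewer than 10 libraries in a group, the adjusted p-values rest on the spread pooled over the groups. No 2 libraries of a group agreed within counting error: the chi-square per degree of freedom of each pair was at least 9.07, where counting error alone gives 1. It reached 116 in females at ZT4 of IUGR-RC. These values were not adjusted for depth. The fit used 1 dispersion per gene for all groups, so its adjusted p-values take no account of unequal spread between groups.

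Before the data were examined, 35 gene lists were written by hand for liver metabolism, stress, hormone and clock pathways and for markers of the liver's cell types. Of their 963 entries 919 matched a symbol of the count table and 2 a synonym. Lists with at least 5 tested genes, 33 of the 35, were tested with camera of limma 3.58.1 at its preset correlation of 0.01, with an estimated correlation and with fry, and p-values were adjusted over the lists of a comparison. Calls within a list were also adjusted over the list alone.

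The genes named were set by a rule written before the data were examined. For a mean over the strata these were the 8 largest rises and the 8 largest falls among called genes with a mean of at least 1 CPM, the same sign in the 4 strata and a gene symbol. For a single stratum or a difference they were the 2 largest in each direction, with CPM of the groups not overlapping in single strata. For each list called by camera they were the 3 members with the smallest p. For the times they were 9 clock genes and the 4 largest in each direction in CON. For the sexes they were 4 genes known to differ, the markers of the sex chromosomes and the 4 largest in each direction.

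The similarity of the HFhf and IUGR-HFhf effects was set against 20 simulations with no true change and against fits in which each comparison had its own part of the CON libraries. A time index placed each library on a line from the mean at ZT4 (0) to the mean at ZT16 (1) of its sex in CON or in its own diet, the library itself left out, over 216 genes outside the clock list, with 0.5 added to CPM before logs were taken. The procedure was tested on simulated data, with counts drawn from each gene's CON mean and fitted dispersion and randomly chosen genes raised or lowered. For HFhf against CON in males at ZT4 it recovered 20.9% of genes changed 1.5-fold, 68.7% at 2-fold and 87.9% at 4-fold, and called 7 of 10633 unchanged genes. For the mean of the 4 strata the shares were 73.1%, 89.6% and 98.5%, with 9 of 10615 unchanged genes called. Each gene was drawn with the same dispersion in all groups, so false calls under unequal spread between groups were not tested. A list raised 1.3-fold was called at an adjusted p of 4.01e-24, or 6.76e-13 with an estimated correlation, and 0 of 29 unchanged lists were called. Genes were drawn independently of each other there, so this cannot show how often the preset correlation gives false calls where genes vary together. In the data the estimated correlation of the fatty acid synthesis list was 0.337 for the mean of HFhf against CON.

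The alternatives set before the data were examined were DESeq2 1.42.0 with its Wald test, RLE size factors, no filter on low counts, edgeR on the compared groups alone, a term for the run of title numbers in the 41 libraries whose titles start with T, and leaving out each library in turn. After seeing the data 2 were added: a fit without the 15 IUGR-RC libraries and a fit without 4 doubted libraries, those with Acta1 above 10 CPM and the library labelled female ZT4 IUGR-RC replicate 3. Coordinates are not printed, since the files identify genes by symbol alone. Intervals and ranges cover counting error and spread between libraries, not shared litters.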

Results

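RNA of 56 livers from adult Sprague-Dawley rat offspring, taken at day 180, was sequenced, and reads were counted per gene. The control group (CON) ate regular chow throughout. The HFhf group was exposed to a high-fat Western diet with fructose in the drinking water, begun in the dams at gestation day 11. The other 2 groups came from dams held to 50% of their calories from gestation day 10 to birth (intrauterine growth restriction, IUGR). After birth these dams were given regular chow (IUGR-RC) or the HFhf diet (IUGR-HFhf). Livers were taken at zeitgeber time 4 (ZT4, in the light phase) or ZT16 (in the dark phase) of a 12 h light and 12 h dark cycle. CON had 3 libraries of each sex at each time. HFhf had 3 of each sex at ZT4 and 4 at ZT16. IUGR-HFhf had 3 in males at ZT4 and 4 in the other strata of sex and time, and IUGR-RC had 3 in females at ZT4 and 4 in the other strata. The libraries held 5.55 M to 19.1 M counted reads, with a median of 9.17 M. The median was 8.54 M in CON, 8.46 M in HFhf, 7.79 M in IUGR-HFhf and 13.4 M in IUGR-RC. Depth was not matched within strata. In females at ZT4 the CON libraries held 16.2 M to 18.7 M. The HFhf libraries there held 5.94 M to 8.68 M and the IUGR-HFhf libraries 7.5 M to 11.1 M. In CON, males held 5.55 M to 9.05 M and females 8.03 M to 18.7 M. The Y-linked transcript Eif2s3y lay between 23.1 and 132 CPM (read counts scaled to library size) in the 28 libraries labelled male, and at most 0.0516 CPM, or 1 read, in the 28 labelled female. The labels name no litters, so littermates could not be taken into account.

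Transcripts of skeletal muscle stood out in single libraries. Acta1, the skeletal muscle actin, was 1310 CPM in female ZT4 IUGR-RC replicate 2, 125 CPM in male ZT16 HFhf replicate 3 and 20.3 CPM in female ZT4 IUGR-HFhf replicate 2, against at most 2.73 CPM in the others. In female ZT4 IUGR-RC replicate 3 genes that differ between the times in the other libraries lay near their ZT16 levels, with an index of 0.968 where 0 is the CON mean at ZT4 and 1 the CON mean at ZT16, against 0.116 and 0.122 in the other libraries of its group. Counts of genes were also made without these 4 libraries, which are called the 4 doubted libraries here.

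The HFhf diet was compared with chow to ask what it changed in the adult liver, first as the mean of the 4 strata of sex and time (14 HFhf and 12 CON libraries). Transcripts of cholesterol synthesis fell together. Of the 27 measured genes of this list 20 fell and 0 rose, and 24 fell when adjusted over the list alone. Sqle, which encodes squalene epoxidase, had a log2 fold change of -2.12 (SE 0.226, adjusted p = 2.02e-08), and Idi1, the isopentenyl diphosphate isomerase, one of -2.09 (SE 0.218, adjusted p = 1.25e-08). Hmgcs1, the cytosolic HMG-CoA synthase, had -1.72 (SE 0.161). In females at ZT16 its level was 744 ± 209 CPM in CON (SD, n = 3) and 142 ± 43.5 CPM in HFhf (SD, n = 4), and it was called in 3 of the 4 strata, not in males at ZT16 (-1.04, adjusted p = 0.082). The list's adjusted p was 3.13e-56 with the preset correlation, and the adjusted p was 0.000135 with an estimated correlation.

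Genes of fatty acid oxidation and targets of the nuclear receptor PPAR alpha rose on HFhf: 22 of 42 rose and 2 fell, or 31 and 2 when adjusted over the list alone. Vnn1, a pantetheinase, had a log2 fold change of 1.33 (SE 0.177), and Acot2, a mitochondrial acyl-CoA thioesterase, 1.06 (SE 0.148). This list's adjusted p was 2.14e-19, and the adjusted p was 0.0302 with an estimated correlation. Of 18 genes of lipid droplets 6 rose and 1 fell, or 9 and 3 when adjusted over the list alone (adjusted p = 0.000186, and adjusted p = 0.0323 with an estimated correlation). Plin2, which coats lipid droplets, had 1.03 (SE 0.145), and in males at ZT16 its level was 134 ± 33.1 CPM in CON (SD, n = 3) and 427 ± 62.9 CPM in HFhf (SD, n = 4). Plin2 was called at ZT16 in both sexes, with 1.68 and 1.46, and not at ZT4, with 0.30 in males (adjusted p = 0.82) and 0.69 in females (adjusted p = 0.33). Apoa4, an apolipoprotein, had 0.92 (SE 0.124), and Mttp, which loads lipid onto apolipoprotein B, had 0.36 (SE 0.059).

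Of 24 genes of fatty acid synthesis 12 rose and 1 fell on HFhf, or 15 and 1 when adjusted over the list alone. Scd2, a stearoyl-CoA desaturase, had a log2 fold change of 2.33 (SE 0.457), Elovl2, a fatty acid elongase, 1.25 (SE 0.192), and Srebf1, the regulator of lipogenic genes, 0.91 (SE 0.154). This list's adjusted p of 4.7e-10 became an adjusted p of 0.083 with an estimated correlation. Pnpla3, a lipid droplet lipase outside that list, had 2.35 (SE 0.543). In the list of fructose and glucose use 7 of 24 rose and 1 fell, or 16 and 1 over the list alone, with 0.67 for Pklr, the liver pyruvate kinase (SE 0.142). In the drug metabolism list 0 of 43 rose and 11 fell, or 2 and 13 over the list alone. Gstm2, a glutathione transferase, had -1.60 (SE 0.196) and was 199 ± 15.1 CPM in CON (SD, n = 3) and 42 ± 6.74 CPM in HFhf (SD, n = 4) in females at ZT16. Gstm2 was called in females, with -2.40 at ZT4 and -2.24 at ZT16, and not in males, with -1.17 (adjusted p = 0.183) and -0.59 (adjusted p = 0.582). Of 26 genes of bile acid and sterol transport 0 rose and 6 fell, or 1 and 7 over the list alone, among them Cyp8b1, the sterol 12 alpha-hydroxylase, at -0.90 (SE 0.181). These 3 lists passed with the preset correlation, and each had an adjusted p of 0.083 with an estimated correlation.

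The unfolded protein response list had 7 genes up and 0 down of 27 on HFhf, or 8 and 0 over the list alone (adjusted p = 0.11 with an estimated correlation). Herpud1, an endoplasmic reticulum stress gene, had a log2 fold change of 0.56 (SE 0.093), and Asns, the asparagine synthetase, 1.64 (SE 0.273). Among 25 genes of gluconeogenesis and amino acid breakdown 1 rose and 9 fell, or 2 and 15 over the list alone (adjusted p = 0.11 with an estimated correlation). Gls2, the liver glutaminase, had -0.53 (SE 0.097), while Pc, the pyruvate carboxylase, had 0.45 (SE 0.069). Of 26 genes of NRF2 and oxidative stress 1 rose and 5 fell, or 1 and 9 over the list alone (adjusted p = 0.145 with an estimated correlation), with -1.98 for Gsta3, another glutathione transferase (SE 0.261). The largest rises and falls outside these lists included Foxp2, a transcription factor, at 3.26 (SE 0.359, adjusted p = 2.14e-08), and Mab21l3 at -3.26 (SE 0.324, adjusted p = 3.83e-09). Marco, a scavenger receptor of macrophages, had -3.03 (SE 0.352, adjusted p = 1.32e-07), while the macrophage list had 0 of 24 genes up and 1 down. Over the 11047 genes tested, 476 rose and 401 fell at an adjusted p under 0.05 in edgeR's quasi-likelihood test.

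**Figure D1:**
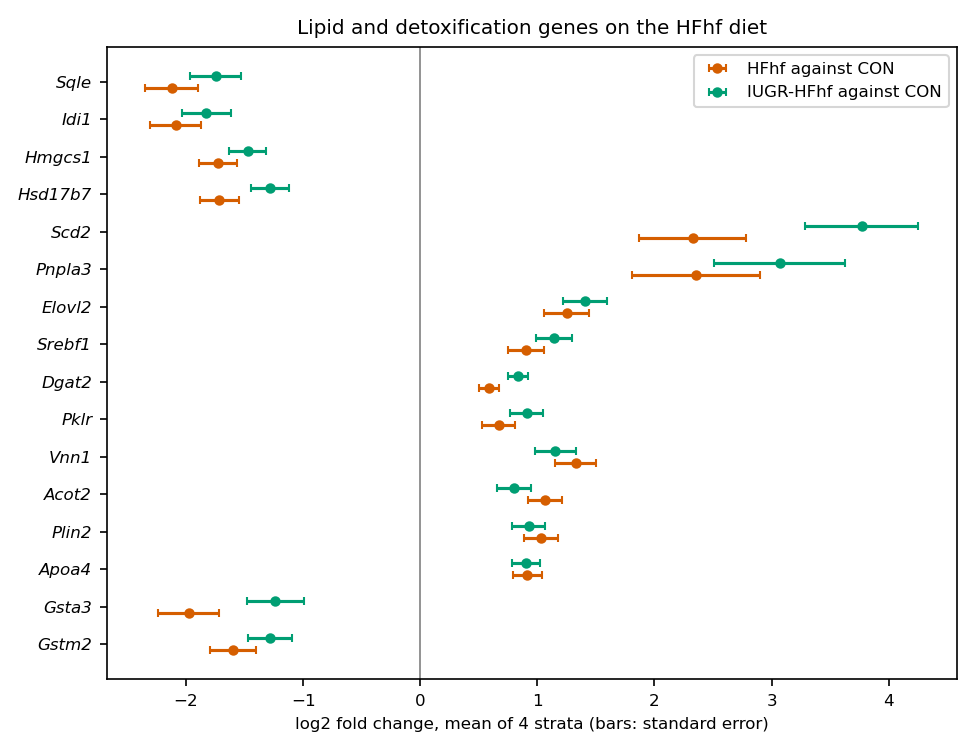
The log2 fold change against CON of 16 genes of lipid and drug metabolism as the mean of the 4 strata of sex and time, with bars of 1 standard error, for HFhf (14 libraries) and IUGR-HFhf (15 libraries) against 12 CON libraries. Genes of cholesterol synthesis such as Sqle (-2.12 in HFhf) lie left of 0, and genes such as Scd2 (2.33 in HFhf, 3.77 in IUGR-HFhf) lie right of it.

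The same diet after growth restriction before birth (IUGR-HFhf, 15 libraries) was compared with CON in the same way. Of 24 genes of fatty acid synthesis 18 rose and 0 fell, or 20 and 0 when adjusted over the list alone. Scd2 had a log2 fold change of 3.77 (SE 0.482, adjusted p = 6.9e-07), Srebf1 1.15 (SE 0.153) and Dgat2, which makes triglycerides, 0.83 (SE 0.083). In females at ZT16 Scd2 was 76.9 ± 53.8 CPM in CON (SD, n = 3) and 1340 ± 531 CPM in IUGR-HFhf (SD, n = 4), and it was called in 3 of the 4 strata, not in males at ZT4 (2.46, adjusted p = 0.258). The list's adjusted p was 6.1e-29, and the adjusted p was 0.00287 with an estimated correlation. In the list of fructose and glucose use 13 of 24 rose and 0 fell, or 17 and 1 over the list alone, with 0.91 for Pklr (SE 0.141); its adjusted p was 0.0411 with an estimated correlation.

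Cholesterol synthesis had 14 of 27 genes down and 0 up in IUGR-HFhf, or 16 and 0 over the list alone (adjusted p = 5.58e-18, and adjusted p = 0.0607 with an estimated correlation). Idi1 had a log2 fold change of -1.83 (SE 0.21) and Hmgcs1 -1.47 (SE 0.156). Fatty acid oxidation and PPAR alpha targets had 19 of 42 genes up and 2 down, or 27 and 3 over the list alone (adjusted p = 0.0718 with an estimated correlation), with 1.06 for Acaa1b, a peroxisomal thiolase (SE 0.136). Of 55 genes of oxidative phosphorylation 19 rose and 0 fell, or 24 and 0 over the list alone (adjusted p = 0.226 with an estimated correlation), by small amounts such as 0.46 for Cox8a of complex IV (SE 0.072). Pck1, the gluconeogenic enzyme, had -1.44 (SE 0.255), and Hsd11b1, which regenerates active glucocorticoid, -1.62 (SE 0.288). In the drug metabolism list 14 of 43 fell and 1 rose, or 17 and 3 over the list alone (adjusted p = 0.18 with an estimated correlation), with -1.28 for Gstm2 (SE 0.189). The interferon list had 8 of 31 down and 2 up, or 12 and 2 over the list alone (adjusted p = 0.469 with an estimated correlation). Marco had -3.10 (SE 0.342), Foxp2 3.42 (SE 0.345) and Mab21l3 -2.41 (SE 0.258). In all, 641 genes rose and 517 fell at an adjusted p under 0.05 in edgeR's quasi-likelihood test.

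The changes of HFhf and IUGR-HFhf against CON went together across genes. Of the genes called, 326 were higher and 259 lower in both comparisons and 0 went opposite ways, against 27.6 and 18.8 if the calls were independent; sharing controls makes them dependent. Pearson's r of the log2 fold changes over 11047 genes was 0.805, with a covariance of 0.0996; genes are not independent replicates. Both comparisons share the CON libraries, and with no true change this alone gave a median r of 0.527 and a covariance of 0.0170 in 20 simulations. With the CON libraries divided between the comparisons the median r was 0.613 and the covariance 0.0968, and a median of 106 genes were higher and 89.5 lower in both, with fewer controls in each comparison.

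Growth restriction before birth was addressed on the HFhf diet by comparing IUGR-HFhf with HFhf, groups that also differed in the dams' diet during gestation. Genes of cholesterol synthesis lay higher in IUGR-HFhf: 0 of 27 passed over all genes, but 20 rose and 0 fell when adjusted over the list alone, with a median log2 fold change of 0.31. Its adjusted p was 2.21e-25, and the adjusted p was 0.0172 with an estimated correlation. Fatty acid synthesis had 0 of 24 over all genes and 9 up and 0 down over the list alone (adjusted p = 0.0172 with an estimated correlation), with values of 0.82 for Fasn, the fatty acid synthase (SE 0.228, adjusted p = 0.234), and 1.44 for Scd2 (SE 0.412, adjusted p = 0.243). In females at ZT16 the same lists passed as well, cholesterol synthesis with 18 genes up over the list alone (adjusted p = 0.0138 with an estimated correlation) and fatty acid synthesis with 11 (adjusted p = 0.0182 with an estimated correlation), and neither passed with an estimated correlation in the other 3 strata. In that group the cholesterol gene Idi1 was 58.7 CPM in female ZT16 IUGR-HFhf replicate 1 and 20.7 to 24.8 CPM in the others. Single genes were few: 4 rose and 2 fell in the mean of the strata in edgeR's test. Pde8b, a phosphodiesterase, had 0.82 (SE 0.141, adjusted p = 0.00266), and Abhd3, a phospholipase, had -4.12 (SE 0.634, adjusted p = 0.00118). Of single strata Abhd3 was called in females at ZT4 alone, with -6.54, where it was 22.7 ± 20 CPM in HFhf (SD, n = 3) and 0.235 ± 0.174 CPM in IUGR-HFhf (SD, n = 4), and in females at ZT16 it had -0.55 (adjusted p = 0.995). In single strata edgeR called 0 genes in males at ZT4 (819 at an unadjusted p under 0.05, and 3 with DESeq2), 2 in males at ZT16, 2 in females at ZT4 and 1 in females at ZT16. The count of 6 became 22 without male ZT16 HFhf replicate 3, and the 2 in males at ZT16 became 24; with 1 library left out the mean count ranged from 3 to 22. The median 95% interval of a gene reached 0.192 to 0.201 to each side in comparisons of means and 0.353 to 0.42 in single strata, on the log2 scale.

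Growth restriction followed by chow (IUGR-RC, 15 libraries) was compared with CON to ask what growth restriction before birth left in the adult liver. Transcripts known to carry no poly(A) tail were far lower in IUGR-RC. Rmrp, the RNA of the ribonuclease MRP, had a log2 fold change of -8.31 (SE 0.228, adjusted p = 4.96e-31), and it lay between 2.29 and 10.5 CPM in the 15 IUGR-RC libraries against 743 to 4070 CPM in the 41 others. Terc, the telomerase RNA, had -4.73 (SE 0.332). Of 18 histone genes, mostly of the kind transcribed in replicating cells, 13 fell and 2 rose, with a median of -3.92 and with -6.60 for Hist2h4 (SE 0.25) and -4.95 for Hist1h1d (SE 0.136). The cell division list had 2 genes up and 5 down of 30, with a median of 0.0524, and 6 histone variants known to be polyadenylated had a median of 0.341. The IUGR-RC libraries also carried titles of a separate number series and had a higher median depth (13.4 M against 8.24 M in the 41 others), with ranges of 5.55 M to 19.1 M and 5.55 M to 18.7 M.

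**Figure D2:**
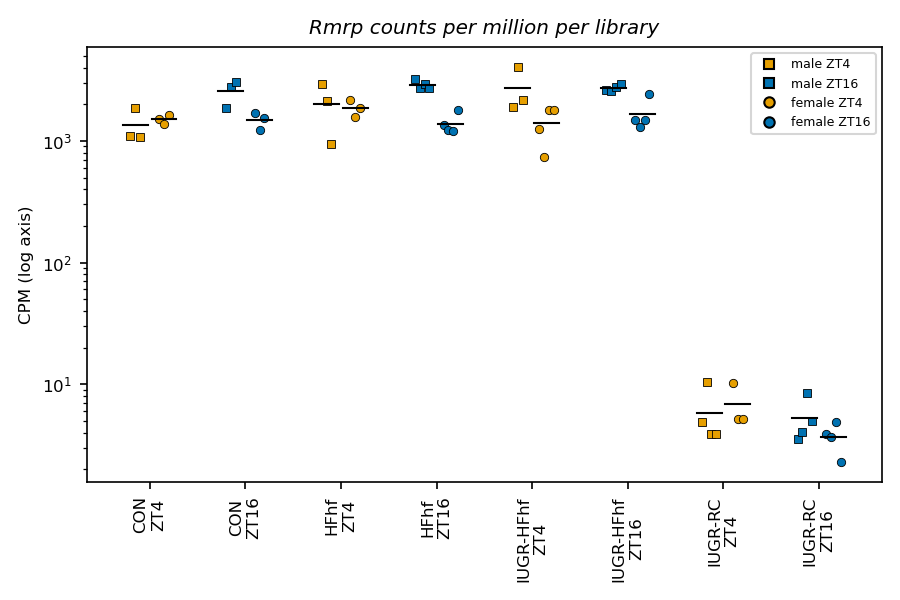
Rmrp in CPM on a log axis, 1 point per library, by diet, sex and time. The 15 IUGR-RC libraries lie between 2.29 and 10.5 CPM and the 41 other libraries between 743 and 4070 CPM.

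Protein-coding groups differed between IUGR-RC and CON as well. No CON library carried a title of the IUGR-RC number series, so a library batch and the diet history cannot be told apart. The changes below are therefore not assigned to growth restriction. Of 63 genes of the cytosolic ribosome 44 rose and 5 fell, or 47 and 5 over the list alone (adjusted p = 0.515 with an estimated correlation), with log2 fold changes of 1.06 for Rpsa (SE 0.056), 1.31 for Rps3 (SE 0.075) and 2.71 for Rpl26 (SE 0.197). Of 55 genes of oxidative phosphorylation 48 rose and 3 fell (adjusted p = 0.61 with an estimated correlation), with 0.91 for Ndufa8 of complex I (SE 0.059). Heat shock had 14 of 19 up and 0 down, with 1.61 for the mitochondrial chaperonin Hspe1 (SE 0.134). The macrophage list had 17 of 24 up and 1 down, with 0.88 for the complement gene C1qa (SE 0.103). Drug metabolism had 23 of 43 up and 4 down, and fatty acid oxidation 25 of 42 up and 2 down. Except for the ribosome, the counts adjusted over the list alone were the same. These last 4 lists each had an adjusted p of 0.902 with an estimated correlation, and each of the 6 lists passed with the preset correlation. In edgeR's test 3648 genes rose and 3298 fell. The counts in single strata were 5159 and 4171 in males at ZT4 and ZT16 and 4207 and 2691 in females. With the compared groups fitted alone the count was 2635 in males at ZT16 and 2265 in females at ZT4, and without the 4 doubted libraries it was 2804 in females at ZT4.

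The times of day were compared within each diet to ask whether the liver clock ran alike. Dbp, an output gene of the clock, rose from ZT4 to ZT16 by a log2 fold change of 4.50, and Per3, a period gene, by 4.19, while Npas2 had -6.85 and Arntl, the BMAL1 gene, -3.28, as means of both sexes. Of the 17 clock genes 11 were higher and 4 lower at ZT16 in CON, and as many over the list alone (adjusted p = 2.13e-06, and adjusted p = 0.0376 with an estimated correlation). On HFhf the ZT16 to ZT4 difference as the mean of both sexes was -1.30 for Dbp, -0.03 for Arntl and -4.58 for Nr1d1, the REV-ERB alpha gene, against 0.03 for Nr1d1 in CON. By sex on HFhf, Dbp had -2.75 in males (adjusted p = 0.0433) and 0.16 in females (adjusted p = 0.943), and Arntl 1.19 in males (adjusted p = 0.236) and -1.25 in females (adjusted p = 0.138). Nr1d1 had -5.75 in males and -3.41 in females. As means of both sexes the differences from CON passed the test, at -5.80 for Dbp (SE 0.902, adjusted p = 0.000251), 3.26 for Arntl (SE 0.589, adjusted p = 0.00145) and -4.61 for Nr1d1 (SE 0.557, adjusted p = 3.34e-06). IUGR-HFhf differed from CON by -4.97 for Dbp (SE 0.878, adjusted p = 0.00258), -3.33 for Nr1d1 (SE 0.524, adjusted p = 0.000608) and 2.50 for Arntl (SE 0.577, adjusted p = 0.0273). Per2 differed by -0.37 on HFhf (adjusted p = 0.919).

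The levels behind these differences moved both ways, though not each shift passed the test. As means of both sexes on HFhf, Dbp passed at ZT4 (3.73) and ZT16 (-2.07). Arntl passed at ZT16 (2.11) and not at ZT4 (-1.14, adjusted p = 0.12). In IUGR-HFhf Dbp passed at ZT4 (3.70) and not at ZT16 (-1.27, adjusted p = 0.148). Arntl there passed at ZT16 (1.60) and not at ZT4 (-0.905, adjusted p = 0.221). In males Dbp was 4.84 ± 1.48 CPM in CON (SD, n = 3) and 93.8 ± 29.5 CPM in HFhf (SD, n = 3) at ZT4, and 85.3 ± 46.4 (SD, n = 3) and 13.9 ± 3.15 CPM (SD, n = 4) at ZT16. Arntl was 54.6 ± 6.00 CPM in CON (SD, n = 3) and 15.8 ± 4.05 CPM in HFhf (SD, n = 3) in males at ZT4, and 7.04 ± 4.09 (SD, n = 3) and 35.8 ± 5.43 CPM (SD, n = 4) at ZT16. In females Dbp was 3.67 ± 0.176 CPM in CON (SD, n = 3) and 33.3 ± 34.6 CPM in HFhf (SD, n = 3) at ZT4, and 109 ± 29.8 (SD, n = 3) and 37.6 ± 15.8 CPM (SD, n = 4) at ZT16. Arntl in females was 55.4 ± 2.91 CPM in CON (SD, n = 3) and 39.6 ± 13.7 CPM in HFhf (SD, n = 3) at ZT4, and 4.19 ± 2.88 (SD, n = 3) and 16.6 ± 3.88 CPM (SD, n = 4) at ZT16. Nr1d1 at ZT4 was higher than in CON by 2.07 on the log2 scale on HFhf (adjusted p = 0.000696) and by 1.94 in IUGR-HFhf (adjusted p = 0.0017). At ZT16 it was lower by 2.53 on HFhf (adjusted p = 0.000105) and lower by 1.39 in IUGR-HFhf (adjusted p = 0.0129). In IUGR-RC the time difference moved by -3.36 for Dbp (adjusted p = 0.0304) and by -3.22 for Ciart, a repressor of the clock (adjusted p = 0.0391). Neither was called without female ZT4 IUGR-RC replicate 3, where the values were -1.50 for Dbp (adjusted p = 0.33) and -1.85 for Ciart (adjusted p = 0.314). Over all genes the difference between times was altered for 44 genes upward and 30 downward on HFhf, 34 and 37 in IUGR-HFhf and 156 and 152 in IUGR-RC. With 1 library left out these totals of 74, 71 and 308 ranged over 41 to 86, 30 to 112 and 29 to 1479, the lowest without female ZT16 CON replicate 3 for HFhf and IUGR-HFhf, without male ZT4 CON replicate 1 as well for IUGR-HFhf, and without female ZT4 IUGR-RC replicate 3 for IUGR-RC. Without the 4 doubted libraries the IUGR-RC total was 69 and the IUGR-HFhf total 126. With the compared groups fitted alone the totals were 137 for HFhf, 223 for IUGR-HFhf and 7 for IUGR-RC, and with DESeq2 116, 182 and 618. For HFhf and IUGR-HFhf they were 136 and 188 with a term for the run of title numbers and 141 and 217 without IUGR-RC, and for IUGR-RC 198 with no filter.

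**Figure D3:**
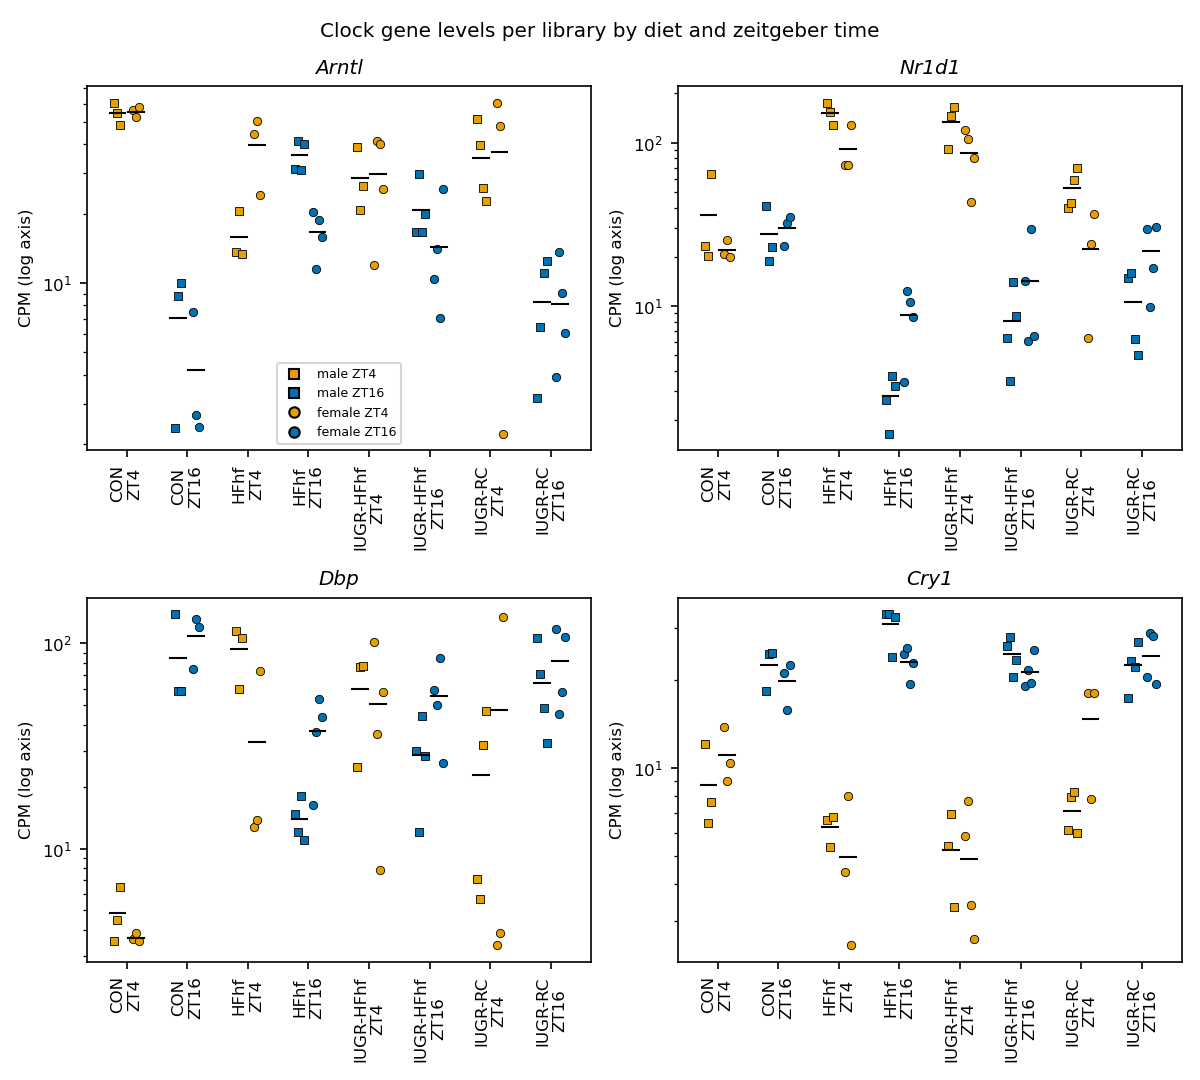
Arntl, Nr1d1, Dbp and Cry1 in CPM on a log axis, 1 point per library, by diet and time (squares male, circles female, orange ZT4, blue ZT16, black bars group means). In CON Dbp lies higher at ZT16 than at ZT4, and in HFhf its ZT16 to ZT4 difference is -1.30 on the log2 scale as the mean of both sexes.

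Other gene groups also differed between the times. Heat shock transcripts were higher at ZT16 in each diet, 11 of 19 in CON, 10 in HFhf, 12 in IUGR-HFhf and 10 in IUGR-RC, with 0 lower, or 12, 13, 16 and 10 over the list alone. With an estimated correlation the adjusted p was 0.137, 0.186, 0.1 and 0.718 in turn. In IUGR-HFhf 34 of 55 genes of oxidative phosphorylation were higher at ZT16 and 0 lower, or 38 and 0 over the list alone (adjusted p = 0.276 with an estimated correlation). In the same diet 15 of 31 interferon genes were lower at ZT16 and 0 higher, or 16 and 0 over the list alone (adjusted p = 0.483 with an estimated correlation), as were 17 of 33 fibrosis genes with 1 higher, or 19 and 1 over the list alone (adjusted p = 0.276 with an estimated correlation). Lower there too were 12 of 23 immediate early genes, 8 of 18 endothelial genes and 6 of 16 genes of antigen presentation, with 0 higher. With an estimated correlation their adjusted p was 0.276, 0.276 and 0.401. By edgeR 690 genes were higher and 763 lower at ZT16 in CON, 601 and 527 in HFhf, 1481 and 1357 in IUGR-HFhf and 1038 and 1170 in IUGR-RC. The HFhf total of 1128 became 729 without male ZT4 HFhf replicate 1 and 746 without female ZT4 HFhf replicate 3, and the IUGR-RC total of 2208 became 1347 without the 4 doubted libraries and 828 with the compared groups fitted alone.

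Males and females were compared in CON, and the diet effects were then compared between the sexes. In CON the male-specific Cyp2c11 was 2000 ± 110 CPM in males and 0.506 ± 0.383 CPM in females at ZT4 (SD, n = 3 each), and the female-specific Cyp2c12 was 147 ± 46 and 4360 ± 554 CPM (SD, n = 3 each). Of the male-biased list 12 of 15 genes were higher in males and 1 lower, and as many over the list alone (adjusted p = 3.83e-12 with an estimated correlation). Of the female-biased list 12 of 17 were lower in males and 2 higher, or 13 and 2 over the list alone (adjusted p = 0.000178 with an estimated correlation). Cholesterol synthesis had 16 of 27 lower in males and 0 higher, or 18 and 0 over the list alone (adjusted p = 0.619 with an estimated correlation). In all 867 genes were higher and 923 lower in males by edgeR.

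Differences between the sexes are the change in males minus that in females. The effect of IUGR-HFhf differed between the sexes for the female-biased list. There 3 of 17 genes had a more positive change in males and 0 a more negative one, or 8 and 0 over the list alone (adjusted p = 0.0436 with an estimated correlation). Sult2a6, a sulfotransferase of this list, differed by 2.49 on the log2 scale. The effect on Mab21l3 differed between the sexes by 4.21 on HFhf (SE 0.704, adjusted p = 0.00476), where in females at ZT4 it was 13.4 ± 7.33 CPM in CON (SD, n = 3) and 0.144 ± 0.027 CPM in HFhf (SD, n = 3). Slc22a25, an anion transporter, differed by -4.97 in IUGR-HFhf (adjusted p = 0.00286). Over all genes the effects differed between the sexes for 8 genes on HFhf, 31 in IUGR-HFhf and 0 in IUGR-RC by edgeR, where 683, 736 and 1623 had an unadjusted p under 0.05 and DESeq2 called 54, 63 and 48. With 1 library left out these counts ranged over 1 to 17, 19 to 35 and 0 to 234, the 234 without female ZT4 IUGR-RC replicate 3.

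Within single strata the HFhf effect was examined next. In females at ZT16 cholesterol synthesis had 16 of 27 genes down and 0 up, or 23 and 0 over the list alone (adjusted p = 0.000142 with an estimated correlation), with -2.39 for Hmgcs1 (SE 0.309). In the same stratum fatty acid oxidation had 10 of 42 up and 1 down, or 20 and 1 over the list alone (adjusted p = 0.0241 with an estimated correlation), with 2.08 for Vnn1. Cyp8b1, counted in that list, had -1.86. In females at ZT4 cholesterol synthesis had 9 of 27 down and 0 up, or 17 and 0 over the list alone (adjusted p = 0.0333 with an estimated correlation). The unfolded protein response had 2 of 27 up and 0 down there, or 14 and 0 over the list alone (adjusted p = 0.0373 with an estimated correlation), with 0.80 for Herpud1, whose call ended under 5 of 13 other settings. Foxp2 in females at ZT16 was 0.0751 ± 0.0794 CPM in CON (SD, n = 3) and 4.05 ± 1.81 CPM in HFhf (SD, n = 4). In males no list passed with an estimated correlation; Srebf1 at ZT16 was 497 ± 94.2 CPM in CON (SD, n = 3) and 1370 ± 188 CPM in HFhf (SD, n = 4). By edgeR 32 genes rose and 44 fell in males at ZT4, 65 and 38 in males at ZT16, 63 and 65 in females at ZT4 and 65 and 74 in females at ZT16. With 1 library left out these totals ranged over 2 to 84, 2 to 115, 32 to 105 and 58 to 137, the lowest without male ZT4 HFhf replicate 1, male ZT16 CON replicate 1, female ZT4 HFhf replicate 3 and female ZT16 CON replicate 2. The balance of rises and falls turned round in some of these fits. In males at ZT16 it was 13 up and 22 down without CON replicate 2, and in males at ZT4 6 up and 3 down without HFhf replicate 3. Without the 4 doubted libraries, none of them from males at ZT4, the total of 76 in males at ZT4 was 131. It was 158 with the compared groups fitted alone and 31 with no filter. The totals of 76, 103 and 128 in males at ZT4, males at ZT16 and females at ZT4 became 146, 209 and 203 with DESeq2, 154, 183 and 248 with a term for the run of title numbers and 162, 200 and 208 without IUGR-RC, and the 103 was 65 with no filter.

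The IUGR-HFhf effect in single strata was largest in number at ZT16. In males at ZT16 fatty acid synthesis had 12 of 24 genes up and 0 down, or 21 and 0 over the list alone (adjusted p = 0.0137 with an estimated correlation), with 2.79 for Me1, the malic enzyme, and 1.54 for Srebf1. In females at ZT16 it had 9 up and 0 down, or 20 and 0 over the list alone (adjusted p = 0.0478 with an estimated correlation). In males at ZT16 the female-biased list had 7 of 17 up and 1 down, and as many over the list alone (adjusted p = 1.05e-05, and adjusted p = 0.141 with an estimated correlation). Sult2a6 was 26.1 ± 11.9 CPM in CON (SD, n = 3) and 272 ± 135 CPM in IUGR-HFhf (SD, n = 4), and Cyp17a1, a steroid hydroxylase, was 5.60 ± 1.49 and 67.2 ± 8.37 CPM in the same libraries. In females at ZT16 the interferon list had 10 of 31 down and 0 up, or 16 and 0 over the list alone (adjusted p = 5.36e-17, and adjusted p = 0.0759 with an estimated correlation). Irf7, a transcription factor of the interferon response, was 28.6 ± 2.37 CPM in CON (SD, n = 3) and 7.16 ± 1.73 CPM in IUGR-HFhf (SD, n = 4), and Ifit3 had a log2 fold change of -1.63 (SE 0.258). Igf1, the growth factor, was 615 ± 68.8 and 359 ± 32.6 CPM in the same libraries (adjusted p = 0.00016). By edgeR 24 genes rose and 27 fell in males at ZT4, 203 and 163 in males at ZT16, 35 and 40 in females at ZT4 and 128 and 117 in females at ZT16. With 1 library left out these totals ranged over 3 to 42, 87 to 260, 32 to 85 and 74 to 262, the lowest without male ZT4 CON replicate 2, male ZT16 CON replicate 1, female ZT4 IUGR-HFhf replicate 4 and female ZT16 CON replicate 3. Without the 4 doubted libraries the total of 75 in females at ZT4 was 129, and with DESeq2 142. The total of 51 in males at ZT4 was 103 with DESeq2 and with the compared groups fitted alone, 106 with a term for the run of title numbers and without IUGR-RC, and 30 with no filter. The total of 366 in males at ZT16 was 673 with the compared groups fitted alone, and the 245 in females at ZT16 was 368 with a term for the run of title numbers and 374 without IUGR-RC.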

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

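The tests of poly(A) selection, of a swap with a ZT16 library, of a smaller amplitude and of an earlier phase or later hour were chosen after the results they concern were seen. The other tests and the splits of the libraries were set before their results were seen.

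Libraries in groups of 4 were compared with their group for 17 measures, in 134 pairs of measure and group, and 10 stood apart by a wide gap to the nearest other library; chance alone gives such a gap in about 1 in 20 groups. Male ZT16 HFhf replicate 3 had Cry1 at 24 CPM against 32.9 to 33.6 in the others of its group, Scd2 at 212 CPM against 42.6 to 61.1, and Acta1 at 125 CPM against 0 to 0.439. Female ZT4 IUGR-HFhf replicate 2 had Acta1 at 20.3 CPM against 0 to 0.162. At the floor of the counts, Acta1 was 0.186 CPM in male ZT16 IUGR-RC replicate 4, 0.0638 CPM in female ZT16 IUGR-HFhf replicate 3 and 0.0661 CPM in female ZT16 HFhf replicate 1, against 0 in the others of each group. Where the others are at 0 any read gives such a gap, so the share of 1 in 20 does not hold for these values. Rmrp was 10.5 CPM in male ZT4 IUGR-RC replicate 2 against 3.9 to 4.84, and 2450 CPM in female ZT16 IUGR-HFhf replicate 4 against 1290 to 1480. Idi1 was 58.7 CPM in female ZT16 IUGR-HFhf replicate 1 against 20.7 to 24.8.

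The tests of a difference between sexes or times found genes in 5 comparisons. The diet effect differed between the sexes for 8 genes in HFhf and for 31 in IUGR-HFhf. It differed between the times for 74 genes in HFhf, 71 in IUGR-HFhf and 308 in IUGR-RC.

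A first pattern is the large shift of IUGR-RC against CON, with 6946 genes called in the mean of the strata. As the source of most of this shift, an effect of restriction before birth that is alike on both later diets is argued against. The slope of the IUGR-HFhf against HFhf changes on the IUGR-RC changes was -0.0134, and lay between -0.0254 and 0.0224 in the strata. A smaller effect of that kind is not excluded, since a library batch could make up most of the IUGR-RC changes. IUGR-HFhf and HFhf also differed in the dams' diet during gestation. Selection of polyadenylated RNA in the IUGR-RC libraries is a candidate explanation for the RNAs without a poly(A) tail, since the median of the histone genes lay -4.26 log2 units from that of the polyadenylated variants. A separate library batch of IUGR-RC gives the same shift in each stratum, and the median correlation between strata was 0.575 (0.481 to 0.757), but no CON library belongs to that batch, so the batch and the diet history cannot be told apart. An effect of growth restriction that needs chow after birth stays open and untested.

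A second pattern is the library labelled female ZT4 IUGR-RC replicate 3, whose clock genes lay at ZT16 levels. A swap with a library of the female ZT16 group is argued against, as the lowest time index of that group was 0.85 on the scale of its own diet. Collection near ZT16 or a wrong time label of this library may explain it: its index over genes outside the clock list was 1.03 on that scale, and on the CON scale 0.968 against 0.116 and 0.122 in the other libraries of its group. No biological explanation was tested for a single animal.

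Another pattern is the clock on the HFhf diets, where levels of several genes lay off those of CON, those of Nr1d1 at both times. A smaller amplitude alone is argued against for Nr1d1 in both diets and for Cry1 on HFhf. These 3 values of clock genes with a called time difference had a change larger in size than in CON. The other clock genes with a called time difference had a change smaller in size, so for them a smaller amplitude is not excluded. This test too was chosen after the pattern was seen, and both diets share the CON libraries. Wrong time labels of whole libraries are argued against too, as the smallest gap between the lowest ZT16 and the highest ZT4 index in a diet and sex was 0.174. An earlier phase of the clock on these diets, or a later hour of collection at both times, stays open. Nr1d1 and Cry1 moved in that direction in 8 of 8 values over both sexes and diets, but these genes were picked after the pattern was seen and both diets share the CON libraries, so this decides nothing.

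Each count of genes was also set against other splits of the same libraries, the real split included. There were 35 splits of 3 and 4 or of 4 and 4 libraries, 10 of 3 and 3, and 100 were drawn where more exist. For the mean of the strata the highest other count was 11 against the real 877 for HFhf, 37 against 1158 for IUGR-HFhf, 3161 against 6946 for IUGR-RC and 7 against 6 for IUGR-HFhf against HFhf. Between the times it was 365 against 1453 in CON, 261 against 1128 in HFhf, 387 against 2838 in IUGR-HFhf and 2763 against 2208 in IUGR-RC, and between the sexes in CON 681 against 1790. For the sex difference it was 21 against 8 in HFhf and 3 against 31 in IUGR-HFhf. For the time difference it was 9 against 74, 31 against 71 and 5502 against 308 in HFhf, IUGR-HFhf and IUGR-RC. Splits with as many genes, the real one included, numbered 2 of 100 for the mean of IUGR-HFhf against HFhf and 2 of 100 for the times in IUGR-RC. They numbered 2 of 100 for the sex difference of HFhf, 4 of 100 for the time difference of IUGR-RC and 1 of 100 in the others. For the means, the times and the sexes in CON the share of such splits was thus under 0.05, not adjusted over the 31 comparisons. The splits treat libraries as exchangeable, and the labels name no litters, so chance differences between litters are not excluded. For the mean of IUGR-HFhf against HFhf and the times in IUGR-RC another split gave more genes than the real one. For the sex and time differences the splits regrouped diet and CON libraries within strata. Such splits test for any diet effect, and cannot tell whether chance gives a difference between sexes or times. The splits for IUGR-RC mix IUGR-RC and CON libraries, so an uneven split can carry the shift between IUGR-RC and CON into the time difference. Counts of several times the real time difference there are therefore no measure of a structure of the samples.

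In 8 comparisons of a single stratum with CON, each with 35 splits, the real count was the highest. It was 103 against 72 for HFhf in males at ZT16 and 139 against 47 in females at ZT16. For IUGR-HFhf it was 366 against 30 in males at ZT16, 75 against 19 in females at ZT4 and 245 against 121 in females at ZT16. For IUGR-RC it was 5159 against 4558 in males at ZT4, 4171 against 3710 in males at ZT16 and 2691 against 1201 in females at ZT16. In these 8 comparisons 1 of the 35 splits, the real one, gave as many genes. That is a share under 0.05, also not adjusted over the comparisons, and chance differences between litters are again not excluded. The 10 splits are too few for such a share for HFhf in males at ZT4 (76, highest other 0) and females at ZT4 (128, highest other 0), IUGR-HFhf in males at ZT4 (51, highest other 0), IUGR-RC in females at ZT4 (4207, highest other 1125) and IUGR-HFhf against HFhf in males at ZT4 (0, highest other 1, with all 10 as large). Chance is not excluded for IUGR-HFhf against HFhf in males at ZT16, where 3 of 35 splits gave 2 or more and the highest other gave 21. Nor is it in females at ZT4 (10 of 35 gave 2 or more, highest other 4) or in females at ZT16 (8 of 35 gave 1 or more, highest other 1). For the sex difference of IUGR-RC the real count was 0 and all 100 splits gave as many, the highest other 3319. These splits too mix IUGR-RC and CON libraries, so a high count can come from the shift between IUGR-RC and CON. For IUGR-HFhf against HFhf in males at ZT16 the split with several times the real count may point to a structure of the samples. Its cause was not tested.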

How the results depend on the processing

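The fit without the 15 IUGR-RC libraries and the fit without the 4 doubted libraries were chosen after seeing the data; the other alternatives were set before. No named gene changed direction between the main fit and another setting where it was called in either. Of 201 comparisons of a count of genes with its value under another setting, 143 stayed within 1.5 times, as did 327 of 446 with 1 library left out. The counts for the means of HFhf, IUGR-HFhf and IUGR-RC against CON, for the times in CON and IUGR-HFhf and for the sexes in CON stayed within 1.5 times in every setting run. RLE factors left every count within 1.5 times and moved the median log2 fold change of all genes by at most 0.0235 in size. For the 811 values of named genes, other settings left 5077 on the same side of the threshold, while 178 newly passed and 166 no longer did. With 1 library left out these were 9458, 63 and 652. Values that passed in neither fit were counted as the same whatever their sign. Among genes named for means, H19 in IUGR-HFhf lost its call in 19 of 34 settings, and Plcd3 in IUGR-HFhf against HFhf in 27 of 36. The correlation of the HFhf and IUGR-HFhf changes was 0.613 with the controls divided between the comparisons. The number-run term and the fit without IUGR-RC cannot be run for comparisons that hold IUGR-RC. No paired analysis was possible because the labels share no replicate numbers between groups. With 1 library left out of a group of 3, the spread is pooled over the groups in the edgeR fit. The cause was not tested where a count moved with DESeq2, with the filter or with a term. Leaving out libraries or fitting the compared groups alone also leaves fewer libraries to estimate the spread. With the compared groups alone counts rose as well as fell. IUGR-HFhf against CON in males at ZT16 went from 366 to 673, and the times in IUGR-RC went from 2208 to 828. The cause of these moves was not tested either. What depth alone limits was not tested, and single strata hold fewer libraries than the means: simulated 1.5-fold changes were recovered for 20.9% of genes in a stratum and 73.1% in a mean. Of the 48 lists called in a mean with the preset correlation, 46 were also called with no filter; hepatocytes in HFhf and lymphocytes in IUGR-HFhf were not.

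For HFhf against CON in males at ZT4 the 76 became 146 with DESeq2, 31 with no filter and 158 with the compared groups alone. The count was 154 with the number-run term and 162 without IUGR-RC. It was 131 without the 4 doubted libraries, none of them in the compared groups, and 2 to 84 with 1 library left out. It was 25, 6 and 19 without CON replicates 1, 2 and 3, and 2 and 9 without HFhf replicates 1 and 3. For HFhf against CON in males at ZT16 the 103 became 209 with DESeq2, 65 with no filter, 183 with the number-run term and 200 without IUGR-RC, and 2 to 115 with 1 library left out. It was 2, 35 and 67 without CON replicates 1, 2 and 3, and 36, 46 and 67 without HFhf replicates 2, 3 and 4. For HFhf against CON in females at ZT4 the 128 became 203 with DESeq2, 248 with the number-run term and 208 without IUGR-RC, and 32 to 105 with 1 library left out. It was 39, 59 and 60 without CON replicates 1, 2 and 3, and 42 and 32 without HFhf replicates 1 and 3. For HFhf against CON in females at ZT16 the 139 became 58 to 137 with 1 library left out. It was 86, 58 and 66 without CON replicates 1, 2 and 3.

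For IUGR-HFhf against CON in males at ZT4 the 51 became 103 with DESeq2, 30 with no filter, 103 with the compared groups alone, 106 with the number-run term and 106 without IUGR-RC, and 3 to 42 with 1 library left out. It was 24, 3 and 18 without CON replicates 1, 2 and 3, and 7 and 10 without IUGR-HFhf replicates 2 and 3. For IUGR-HFhf against CON in males at ZT16 the 366 became 673 with the compared groups alone, and 87 to 260 with 1 library left out. It was 87 and 144 without CON replicates 1 and 2, and 227 and 230 without IUGR-HFhf replicates 1 and 4. For IUGR-HFhf against CON in females at ZT4 the 75 became 142 with DESeq2 and 129 without the 4 doubted libraries, and 32 to 85 with 1 library left out. It was 36, 41 and 45 without CON replicates 1, 2 and 3, and 48 and 32 without IUGR-HFhf replicates 1 and 4. For IUGR-HFhf against CON in females at ZT16 the 245 became 368 with the number-run term and 374 without IUGR-RC, and 74 to 262 with 1 library left out. It was 103 and 74 without CON replicates 2 and 3, and 139 without IUGR-HFhf replicate 2.

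For IUGR-RC against CON in males at ZT16 the 4171 became 2635 with the compared groups alone. For IUGR-RC against CON in females at ZT4 the 4207 became 2265 with the compared groups alone and 2804 without the 4 doubted libraries. For the times in HFhf the 1128 became 729 to 1175 with 1 library left out. It was 729 without male ZT4 HFhf replicate 1, and 746 without female ZT4 HFhf replicate 3. For the times in IUGR-RC the 2208 became 828 with the compared groups alone and 1347 without the 4 doubted libraries.

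For IUGR-HFhf against HFhf in males at ZT4 the 0 became 3 with DESeq2 and 1 with the compared groups alone, and 0 to 2 with 1 library left out. It was 2 without IUGR-HFhf replicate 1. For IUGR-HFhf against HFhf in males at ZT16 the 2 became 0 with the compared groups alone, 1 with the number-run term and 24 without the 4 doubted libraries, and 0 to 24 with 1 library left out. It was 0, 0 and 1 without IUGR-HFhf replicates 1, 2 and 3, and 0, 0, 24 and 1 without HFhf replicates 1, 2, 3 and 4. For IUGR-HFhf against HFhf in females at ZT4 the 2 became 11 with DESeq2, 9 with no filter, 0 with the compared groups alone and 9 without the 4 doubted libraries, and 0 to 9 with 1 library left out. It was 1 and 0 without IUGR-HFhf replicates 2 and 3, and 5, 9 and 7 without HFhf replicates 1, 2 and 3. For IUGR-HFhf against HFhf in females at ZT16 the 1 became 11 with DESeq2 and 5 with the compared groups alone, and 0 to 2 with 1 library left out. It was 0 without IUGR-HFhf replicates 1, 2, 3 and 4, and 2 and 0 without HFhf replicates 1 and 3. For the mean of IUGR-HFhf against HFhf the 6 became 18 without the 4 doubted libraries, and 3 to 22 with 1 library left out. It was 3 without male ZT4 IUGR-HFhf replicate 2, and 3 without male ZT4 HFhf replicate 3. The count was 22 and 3 without male ZT16 HFhf replicates 3 and 4, and 3 without female ZT4 IUGR-HFhf replicate 3. The count was 3 without female ZT4 HFhf replicate 1, and 3 without female ZT16 IUGR-HFhf replicate 2. The count was 3 without female ZT16 HFhf replicate 3.

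For the sex difference of HFhf the 8 became 54 with DESeq2, 16 with the compared groups alone and 15 without IUGR-RC, and 1 to 17 with 1 library left out. It was 3 and 4 without male ZT4 CON replicates 2 and 3, and 4, 17 and 3 without male ZT4 HFhf replicates 1, 2 and 3. The count was 4 without male ZT16 CON replicate 3, and 1 and 5 without female ZT4 CON replicates 1 and 3. The count was 5, 15 and 2 without female ZT4 HFhf replicates 1, 2 and 3, and 1 without female ZT16 HFhf replicate 3. For the sex difference of IUGR-HFhf the 31 became 63 with DESeq2, and 19 to 35 with 1 library left out. It was 20 without female ZT4 CON replicate 1, and 19 without female ZT16 CON replicate 3. For the sex difference of IUGR-RC the 0 became 48 with DESeq2, and 0 to 234 with 1 library left out. It was 32 and 2 without male ZT4 IUGR-RC replicates 2 and 3, and 6 without male ZT16 CON replicate 1. The count was 40, 13 and 9 without male ZT16 IUGR-RC replicates 2, 3 and 4, and 73 and 234 without female ZT4 IUGR-RC replicates 1 and 3. The count was 10 without female ZT16 CON replicate 1, and 2 without female ZT16 IUGR-RC replicates 1 and 4.

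For the time difference of HFhf the 74 became 116 with DESeq2, 137 with the compared groups alone, 136 with the number-run term and 141 without IUGR-RC, and 41 to 86 with 1 library left out. It was 47 without male ZT4 HFhf replicate 1, and 47 without male ZT16 CON replicate 1. The count was 41 without female ZT16 CON replicate 3. For the time difference of IUGR-HFhf the 71 became 182 with DESeq2, 223 with the compared groups alone, 188 with the number-run term, 217 without IUGR-RC and 126 without the 4 doubted libraries, and 30 to 112 with 1 library left out. It was 30 and 42 without male ZT4 CON replicates 1 and 3, and 112, 35 and 35 without male ZT4 IUGR-HFhf replicates 1, 2 and 3. The count was 43 and 42 without female ZT4 CON replicates 1 and 2, and 107 without female ZT4 IUGR-HFhf replicate 4. The count was 30 without female ZT16 CON replicate 3. For the time difference of IUGR-RC the 308 became 618 with DESeq2, 198 with no filter, 7 with the compared groups alone and 69 without the 4 doubted libraries, and 29 to 1479 with 1 library left out. It was 119 and 138 without male ZT4 CON replicates 1 and 2, and 168, 661 and 109 without male ZT4 IUGR-RC replicates 1, 2 and 4. The count was 36 without male ZT16 CON replicate 1, and 1479, 163, 107 and 98 without male ZT16 IUGR-RC replicates 1, 2, 3 and 4. The count was 138 and 97 without female ZT4 CON replicates 1 and 3, and 469, 1057 and 29 without female ZT4 IUGR-RC replicates 1, 2 and 3. The count was 133 and 134 without female ZT16 CON replicates 2 and 3.

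Gene lists are counted in the order males at ZT4, males at ZT16, females at ZT4, females at ZT16 and the mean of the strata. For HFhf against CON the lists called numbered 15, 10, 12, 16 and 12, of which 0, 0, 2, 2 and 3 passed with an estimated correlation and 3, 4, 4, 5 and 11 with fry. For IUGR-HFhf against CON the lists called numbered 5, 13, 13, 22 and 15, of which 0, 1, 0, 1 and 2 passed with an estimated correlation and 0, 8, 2, 8 and 12 with fry. For IUGR-RC against CON the lists called numbered 2, 8, 5, 4 and 6, of which 0, 0, 0, 0 and 0 passed with an estimated correlation and 2, 8, 5, 4 and 6 with fry. For IUGR-HFhf against HFhf the lists called numbered 7, 16, 9, 13 and 15, of which 0, 0, 0, 2 and 2 passed with an estimated correlation and 0, 0, 0, 2 and 3 with fry. For ZT16 against ZT4 in CON, HFhf, IUGR-HFhf and IUGR-RC the lists called numbered 3, 12, 12 and 6, of which 1, 0, 0 and 0 passed with an estimated correlation and 2, 9, 12 and 2 with fry. For males against females in CON the lists called numbered 6, of which 2 passed with an estimated correlation and 6 with fry. For the sex difference of HFhf, IUGR-HFhf and IUGR-RC the lists called numbered 10, 6 and 8, of which 0, 1 and 0 passed with an estimated correlation and 0, 1 and 0 with fry. For the time difference of HFhf, IUGR-HFhf and IUGR-RC the lists called numbered 5, 17 and 3, of which 0, 0 and 0 passed with an estimated correlation and 0, 0 and 0 with fry.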

Other observations

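The following values come from gene lists written before the data were examined and from the authors' deposited tables, except for the last sentence. On HFhf, 10 of 55 genes of oxidative phosphorylation rose in the mean of the strata and 0 fell, or 15 and 0 when adjusted over the list alone, with a log2 fold change of 0.39 for Cox8a (SE 0.073). Of 19 hepatocyte markers 3 rose and 0 fell, or 5 and 1 over the list alone, with a log2 fold change of 0.41 for Alb, the albumin gene (SE 0.107). Both lists passed with the preset correlation, and the adjusted p with an estimated correlation was 0.468 and 0.735. With no filter on low counts the hepatocyte list did not pass (adjusted p = 0.058 against 0.0426, both with the preset correlation).

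In IUGR-HFhf further lists passed with the preset correlation and not with an estimated one. Lipid droplets had 5 of 18 genes up and 2 down (adjusted p = 0.102 with an estimated correlation), or 8 and 3 when adjusted over the list alone. Gluconeogenesis and amino acid breakdown had 2 of 25 up and 9 down (adjusted p = 0.164 with an estimated correlation), or 2 and 14 over the list alone. Bile acid and sterol transport had 1 of 26 up and 4 down (adjusted p = 0.164 with an estimated correlation), or 1 and 10 over the list alone. NRF2 and oxidative stress had 3 of 26 up and 7 down (adjusted p = 0.187 with an estimated correlation), or 3 and 10 over the list alone. Glucocorticoid targets had 1 of 23 up and 3 down (adjusted p = 0.268 with an estimated correlation), and lymphocytes 0 of 13 up and 2 down (adjusted p = 0.408 with an estimated correlation), or 1 and 4 over the list alone. With no filter the lymphocyte list did not pass (adjusted p = 0.0522 against 0.0231, both with the preset correlation). Macrophages had 0 of 24 up and 2 down, or 0 and 3 over the list alone, and the cytosolic ribosome 2 of 63 up and 0 down, or 1 and 0 over the list alone (adjusted p = 0.564 with an estimated correlation for each). Nr3c1, the glucocorticoid receptor, had a log2 fold change of -0.29 (SE 0.066). Of the lymphocyte genes, Gzma, a granzyme, lost its call in 8 of 34 other settings and Cxcr3, a chemokine receptor, in 22 of 34.

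For the mean of IUGR-HFhf against HFhf 15 lists passed with the preset correlation, and those other than cholesterol and fatty acid synthesis did not with an estimated one. Markers of cell types were among them. With the preset correlation bile duct cells were higher (adjusted p = 0.0149). Hepatocytes (adjusted p = 0.00642), macrophages (adjusted p = 0.00348) and endothelial cells (adjusted p = 0.0264) were lower. The female-biased list had 0 of 17 genes over all genes, and 2 up and 0 down over the list alone (adjusted p = 0.23 with an estimated correlation), with a log2 value of 0.78 for Sult2a6 (SE 0.203, adjusted p = 0.193). The unfolded protein response had a median of -0.15 (adjusted p = 0.177 with an estimated correlation) and the acute phase one of -0.14 (adjusted p = 0.243 with an estimated correlation), with 0 genes of either past the threshold over all genes or over the list alone.

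Other lists were not called in the means against CON. For HFhf the adjusted p with the preset correlation was 0.617 for the clock (0 of 17 up and 0 down), 0.257 for male-biased genes (2 of 15 up), 0.605 for female-biased genes (1 of 17 up and 3 down), 0.314 for macrophages (0 of 24 up and 1 down) and 0.181 for lymphocytes (0 of 13 up and 1 down). It was 0.617 for antigen presentation, 0.905 for cytokines, 0.884 for fibrosis, 0.222 for endothelial cells, 0.932 for bile duct cells, 0.295 for red blood cells and 0.738 for adipocytes. Further values were 0.181 for heat shock, 0.605 for insulin, growth hormone and IGF, 0.222 for the ribosome, 0.8 for cell division, 0.605 for the acute phase, 0.119 for interferon, 0.769 for immediate early genes, 0.738 for imprinted genes and 0.222 for glucocorticoid targets. For female-biased genes and adipocytes the median log2 fold change was positive, at 0.12 and 0.28, while the test's direction was negative. For IUGR-HFhf the values were 0.172 for the clock, 0.715 for male-biased genes, 0.172 for female-biased genes, 0.135 for antigen presentation, 0.952 for cytokines, 0.677 for fibrosis, 0.997 for endothelial cells, 0.147 for bile duct cells, 0.178 for red blood cells and 0.677 for adipocytes. They were 0.69 for hepatocytes, 0.172 for the unfolded protein response, 0.0633 for heat shock, 0.139 for insulin, growth hormone and IGF, 0.159 for cell division, 0.0623 for the acute phase, 0.249 for immediate early genes and 0.571 for imprinted genes.

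In IUGR-RC against CON the lists not called included antigen presentation with 9 of 16 genes up and 2 down (adjusted p = 0.231), cytokines with 13 of 24 up and 3 down (adjusted p = 0.264), endothelial cells with 5 of 18 up and 9 down (adjusted p = 0.231), and insulin, growth hormone and IGF with 4 of 29 up and 12 down (adjusted p = 0.0976), all with the preset correlation.

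The authors' 12 tables each hold 13485 genes. Their adjusted p was under 0.05 for 135, 203, 211 and 180 genes for HFhf in males at ZT4, males at ZT16, females at ZT4 and females at ZT16. For IUGR-HFhf it was so for 53 higher and 48 lower genes in males at ZT4 and for 459, 145 and 341 genes in the other strata in turn, and for IUGR-RC for 5130, 4145, 4337 and 2679. Of the genes called here for HFhf, 73 of 76 in males at ZT4, all but 2 in males at ZT16, 128 of 128 in females at ZT4 and 138 of 139 in females at ZT16 also had an adjusted p under 0.05 there. For IUGR-HFhf these were 47 of 51, 357 of 366, 74 of 75 and 240 of 245, and for IUGR-RC 4960 of 5159, 4046 of 4171, 3886 of 4207 and 2555 of 2691. Pearson's r of the log2 fold changes across genes lay between 0.831 and 0.960; genes are not independent replicates. Without female ZT4 IUGR-RC replicate 2 the muscle myosin genes Myh1 and Myh2 were not called in females at ZT4, with log2 fold changes of 1.70 and 3.21; both were chosen after their values were seen.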
